A study of Drosophila melanogaster with 2 samples.

How the data were processed

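Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 0 to 24 h, per the labels. The embryos carried a transgene encoding the transcription factor Single-minded (Sim) fused to enhanced green fluorescent protein, and the fusion was precipitated with an antibody against the fluorescent tag, although the antibody entry of the labels reads sim. Chromatin was sonicated, with a stated fragment size range of 200 to 800 bp. The series held 1 group of 2 samples, labelled as biological replicates 1 and 2. Labels name a control experiment, which was not analysed here.

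The authors deposited 8 peak lists in dm6 coordinates. Each replicate had a ranked list and a list thresholded by the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks repeat between 2 sets of calls. Both replicates together gave a conservative IDR list, an optimal IDR list and 2 ranked lists. Every peak of the conservative list was found in one of these ranked lists, and every peak of the optimal list in the other. The deposited score is the scaled IDR, per the values in the lists. All 4 thresholded lists had a lowest score of 830, which corresponds to an IDR of 0.0100. The deposited signal value of each peak is the strength assigned by the authors' peak caller, and the lists also carry a deposited −log10 q-value. Both are the authors' own values and served here only to describe, rank or filter peaks within a list. The aligner, the peak caller and their settings are not given in the sources used here. Read counts and sequencing depth were not given in the lists, so the depth is unknown and no interval that needs it is reported. The 2 ranked lists of the whole series carry 8 further columns each with values of the compared sets of calls, which were not used here.

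Peak widths reached exactly 304 bp in the pooled lists, 296 bp in replicate 1 and 280 bp in replicate 2, and the median width equalled this maximum in every list. Positions of summits are therefore the more precise description of a site. Overlapping peaks were left as deposited. Merging them would remove 96 of the 2682 optimal peaks.

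Genes came from the Ensembl release 115 annotation of BDGP6, whose chromosome arms have the lengths of dm6, and bases from the RefSeq copy of the same assembly. No listed peak ended beyond the end of its arm. Pseudogenes and transposable elements were left out, and transcription start sites (TSS) were those of protein-coding transcripts. All 4 thresholded lists held peaks on arms 2L, 2R, 3L, 3R, 4 and X alone. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

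The following choices were made before the data were examined. The optimal list was the principal one. Replicate overlap was the share of the shorter replicate list overlapped by at least 1 bp, set against 1000 random placements within the same arm. Spearman's rho of the signal values described shared peaks. Proximity to a TSS meant a summit within 500 bp, against 1000 random placements of points. The core of the CNS midline element (CME), ACGTG on either strand, was searched within 50 bp of each summit and in a window of equal length 300 bp to one randomly chosen side, and the paired windows were compared by an exact two-sided McNemar test. This pattern was 1 of 15 tested as one family with Benjamini-Hochberg adjustment. All 2080 6-mers, each merged with its reverse complement, were tested in the same way as a second family. Peaks were also divided into 4 parts by signal value, and the strongest and weakest parts were compared by a two-sided Fisher's exact test.

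Gene lists were fixed in advance for the midline, bHLH-PAS factors, trachea, dorsoventral patterning, the EGFR pathway, the Notch pathway, axon guidance, segmentation and Hox genes, neurons, glia, muscle, hemocytes and fat body, epidermis, gut endoderm, germline, ribosomal proteins and heat shock. A gene carried a peak when a summit lay within it or 5 kb either side. The number of such genes in each of the 17 lists was compared with 10000 random lists of protein-coding genes matched in 20 bins of gene length, with a two-sided empirical p adjusted over all lists. The smallest p these draws can give is 2.0e-04. Every adjusted p for a gene list below comes from these permutations. The annotation carries 3 listed genes under other symbols (Delta, hry and nanos). Genes named in the text are those with the TSS nearest to each of the 30 strongest optimal peaks, every midline gene, and up to 4 members of each other list with the strongest best peak. Other genes named below were chosen after their values were seen. Shares of peaks per chromosome arm were given exact binomial intervals, which cover counting error only because neighbouring peaks are not independent.

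The 6-mer test and the gene list test were first tested on simulated data. At random genomic points the 6-mer test made 0 calls among 2080 6-mers, and it recovered 20 of 20 6-mers planted in 5% of windows. Random points lack the difference in GC content between summits (35.9%) and flanks (43.2%) of the peaks, so this simulation does not cover its effect. The gene list test called 1.5% of 200 random lists of 14 genes at an unadjusted p under 0.05, and 100% of 50 lists in which 12 of the 14 genes were given a peak. Smaller excesses were not simulated.

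Alternatives fixed in advance were the conservative list, the stronger part of the optimal list, each replicate's own list, other distances, windows and flanks, and another rule for assigning peaks to genes. Alternatives chosen after seeing the data were merged peaks, genomic windows matched to each summit window on GC content (150000 windows drawn at least 1000 bp from optimal summits, in bins of 3 bases), ranked peaks outside the optimal list as a background for TSS proximity, genes with overlapping windows counted once, matching on the number of TSS within 20 kb, genes extended by 10 kb for the lists other than the midline, and the midline list without sim.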

Results

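ChIP-seq peaks of the Sim fusion protein came from 2 biological replicates of whole embryos aged 0 to 24 h. Sim is a bHLH-PAS transcription factor known as the master regulator of the midline cells of the embryonic central nervous system. It binds DNA together with its partner Tango at the CME. The optimal IDR list held 2682 peaks and the conservative list 2451, with 2120 peaks at identical coordinates in both. Replicate 1 alone gave 1071 peaks and replicate 2 alone gave 1676. Read depth is unknown for both replicates, so the difference between these counts cannot be set against depth.

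The strongest optimal peak lay on X from 2703777 to 2704000, with its summit 39 bp from a TSS of Ugalt, a UDP-galactose transporter gene. Its signal value was 755. The next strongest peaks were nearest to CG14100 on 3L (711, also within 5 kb of the trithorax group gene ash1), px on 2R (683), CenG1A on 2L (643, also within 5 kb of mRpS23) and CG13323 on 2R (609.6). The peak nearest to CG13323 lay between genes, 11922 bp from the TSS. Genes of chromatin regulators were also among the 30 strongest. The Polycomb group gene ph-p had a peak of signal value 609.5 in an intron, Psc had one of 506 between genes 4227 bp from its TSS, and Chro had one of 561 in a 5' UTR. Nearest to the mitochondrial ribosomal protein genes mRpS10 and mRpL41 were peaks of 575 and 570.4. The remaining genes nearest to the 30 strongest peaks were CG18549, CG11050, gish, Fkbp14, Tcs5, PNPase, CG7601, Tina-1, Tlk, hll, CG5611, CG1888, eEF1gamma, CG9147, CG1142, CG12769, tank, Btk, CG31668 and CG32772. Their signal values ranged down to 416. All 30 peaks overlapped a peak in the conservative list and in both replicate lists, and 20 of them had a summit within 500 bp of a TSS. No midline gene was nearest to any of the 30.

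Replicates were compared to learn whether they called the same regions. Of the 1071 replicate 1 peaks, 835 (78.0%) overlapped a replicate 2 peak, against a mean of 0.694% and a maximum of 1.77% over 1000 random placements. The one-sided p of 0.001 is the smallest these placements can give. In the other direction 49.3% of the 1676 replicate 2 peaks overlapped a replicate 1 peak. Of the optimal peaks, 827 (30.8%) overlapped peaks of both replicate lists, 198 of replicate 1 alone, 736 of replicate 2 alone and 921 (34.3%) of neither. Among the 671 optimal peaks with the highest signal value, 91.7% overlapped both lists, compared with 2.09% among the 671 with the lowest. Spearman's rho across the 835 shared peaks was 0.676. It describes peaks, which are not independent replicates, and it was 0.551 when signal values were read from the ranked lists of each replicate at 2649 optimal peaks.

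**Figure D1:**
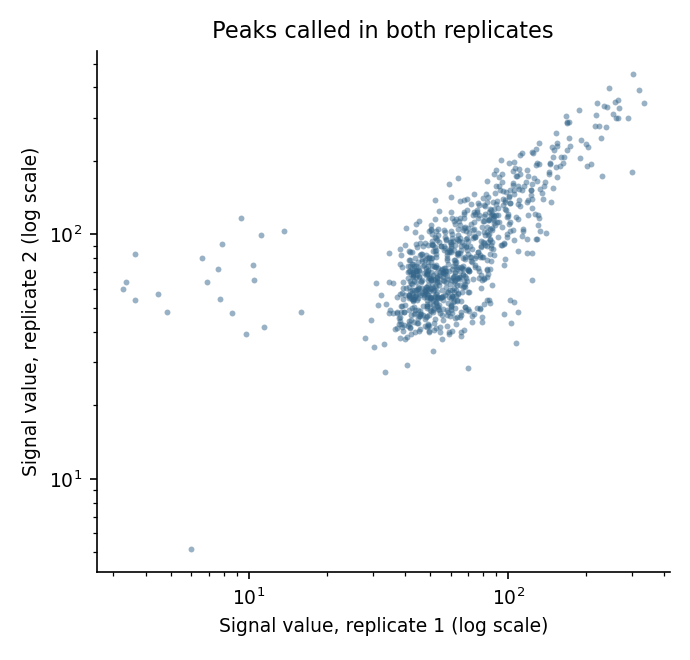
Signal value of each of the 835 replicate 1 peaks that overlap a replicate 2 peak (x axis, log scale) against the highest signal value of the overlapping replicate 2 peaks (y axis, log scale), both in the authors' units. Each point is a peak, and Spearman's rho is 0.676.

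Peak summits were more frequent than random points at promoters, in 5' UTRs and exons outside the coding sequence and UTRs and, by less, in introns and between genes. Within 500 bp of a TSS lay 40.3% of optimal summits, against a mean of 11.5% (SD 0.590) for random points on the same arms. Among summits, 50% were in introns (random mean 42.4%), 9.21% in 5' UTRs (3.38%), 3.17% in exons outside the coding sequence and UTRs (1.62%) and 33.8% between genes (31.0%). Coding sequence held 2.42% of summits against a random mean of 16.8%, and 3' UTRs held 1.42% against 4.89%. For TSS proximity and for each of these features the two-sided permutation p was 0.00200, the smallest that 1000 placements can give. Among the 671 peaks with the highest signal value 47.2% lay near a TSS, compared with 38.3% among the 671 with the lowest.

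Peaks were spread over all chromosome arms. Arm 2L held 19.6% of the optimal peaks (exact 95% interval 18.1% to 21.2%) with 17.6% of the assembled length, and 3L held 22.3% (20.8% to 24.0%) with 21%. Arm 2R held 18.9% (17.5% to 20.5%) with 18.9%, 3R held 22.5% (21.0% to 24.1%) with 24.0%, and X held 16.2% (14.8% to 17.6%) with 17.6%. The small arm 4 held 11 peaks, 0.410% (0.205% to 0.733%), with 1.01% of the length. The X share was 18.5% (16.2% to 20.9%) in replicate 1 and 17.9% (16.1% to 19.8%) in replicate 2. Both shares were above the interval of the optimal list, but their own intervals overlapped it.

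The CME core was searched at summits because it is the known binding sequence of Sim and Tango. ACGTG lay within 50 bp of 195 of the 2682 summits (7.27%) and in 261 of the flanking windows (9.73%). It was thus less frequent at summits, in 172 peaks with the core at the summit alone against 238 with it in the flank alone (exact McNemar adjusted p = 0.00390). The longer form RACGTG was also less frequent, at 4.21% against 5.85% (exact adjusted p = 0.0147). That of RACGTG did not pass in the 1341 strongest peaks (exact adjusted p = 0.193), the replicate 1 list (0.323), windows of 100 bp either side (0.120), summits more than 500 bp from a TSS (0.0528) or merged peaks (0.252). The difference for ACGTG was -2.46 percentage points in the optimal list and larger in the replicate 2 list (-4.71 points, exact adjusted p = 5.7e-06). It did not pass the threshold in the replicate 1 list (-1.77 points, exact adjusted p = 0.290). Nor did it pass in the 1341 optimal peaks with the highest signal value (-2.31 points, exact adjusted p = 0.0786). Against genomic windows of equal GC content, an alternative chosen after seeing the data, the direction turned: 7.27% of summit windows and 6.76% of matched windows held the core (permutation adjusted p = 0.517), as did the direction for RACGTG (4.21% and 4.06%, 0.783).

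Other patterns differed between summits and flanks. The homeodomain pattern TAATTA was more frequent at summits (9.06% against 6.56%, exact adjusted p = 0.00281), as was the Twist E-box CATATG (4.66% against 3.24%, adjusted p = 0.0170). GAGAG, bound by GAGA factor, was less frequent (12.8% against 16.3%, exact adjusted p = 0.00150), as were the Snail E-box CAGGTG (2.20% against 4.25%, adjusted p = 2.36e-04), the Su(H) pattern GTGGGAA (0.634% against 1.53%, adjusted p = 0.00558) and the CA repeat (2.16% against 4.4%, exact adjusted p = 9.49e-05). TACGTG, the palindromic E-box CACGTG, the Zelda, DRE, POU, Sox and Grainyhead patterns did not pass the threshold. In the replicate 2 list CACGTG passed as less frequent (exact adjusted p = 0.00288) and the POU pattern as more frequent (0.0159), and more than 500 bp from a TSS TACGTG (0.0197) and CACGTG (0.0444) passed as less frequent. The result for GAGAG depended on the flank: 1000 bp away the direction turned (12.8% at summits against 12.2%, exact adjusted p = 0.603), and with windows of 100 bp either side the call ended (0.584). In windows of 101 bp centred 100 bp before and after summits, GAGAG was present in 19.5% and 20.2%. The lower share at summits thus lay between higher shares beside them, and GAGAG was not rare around these peaks. CATATG did not pass in the replicate 1 list (exact adjusted p = 0.265), the 1341 strongest peaks (0.201), windows of 25 bp (0.228) or 100 bp (0.119) either side, or against flanks 1000 bp away (0.112). CAGGTG did not pass in the replicate 1 list (exact adjusted p = 0.245), with merged peaks (0.264) or more than 500 bp from a TSS (0.371). TAATTA and GTGGGAA did not pass with windows of 100 bp (exact adjusted p = 0.0645 for each), GTGGGAA with 25 bp (0.228), or the CA repeat against flanks 1000 bp away (0.112). In the single replicate lists the difference for TAATTA was larger (4.01 percentage points in replicate 1 and 5.97 in replicate 2, against 2.50). That for GAGAG was larger too (-7.84 and -8.00, against -3.50). Against windows of equal GC content the direction turned for GAGAG, at 12.8% against 8.83% (permutation adjusted p = 0.00150), for the CA repeat, at 2.16% against 1.47% (0.0150), and for TAATTA, at 9.06% against 9.93% (0.271). CAGGTG (2.20% against 2.71%) and GTGGGAA (0.634% against 0.957%) kept their direction but did not pass there (permutation adjusted p = 0.270 for each), while CATATG (4.66% against 2.99%, permutation adjusted p = 0.00150) and the DRE (0.858% against 0.333%, 0.00200) passed as more frequent.

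Strong peaks did not differ detectably from weak ones in the CME core. Among the 670 peaks with the highest signal value 6.42% held ACGTG within 50 bp of the summit, and among the 670 with the lowest 8.96% did (two-sided Fisher's exact p = 0.100). In the replicate 1 list the order turned (7.87% in the strongest part and 6.37% in the weakest, two-sided Fisher's exact p = 0.614). Of the 30 strongest peaks 2 held it.

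The search over 6-mers was made without assuming a motif. Of 2080 6-mers, 318 were more frequent at summits and 579 less frequent. The words with the smallest p consisted of A and T alone: AAATAT was present in 31.3% of summit windows and 15.7% of flanks (exact adjusted p = 3.00e-37), ATTTAA in 26.7% and 12% (adjusted p = 1.28e-36), and TAAATA in 27.6% and 13.3% (adjusted p = 2.24e-34). Of the 228 6-mers with at least 5 A or T bases, 207 were more frequent at summits, and 12 were so against windows of equal GC content. None of the more frequent 6-mers contained ACGTG. GC content averaged 35.9% (SD 11.0) at summits and 43.2% (SD 9.81) in flanks, and in the 300 strongest peaks it averaged 30.2% and 43.5%. Against windows of equal GC content, chosen after seeing the data, 103 6-mers were more frequent at summits and 87 less frequent. The excess of less frequent words seen against flanks was not found there, but the background and the form of the test both changed. The words with the smallest p were then ACAGTG (6.75% against 3.28%, Fisher's exact adjusted p = 5.74e-12), AGTGTA (7.64% against 4.20%) and ACACTG (6.34% against 3.27%).

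**Figure D2:**
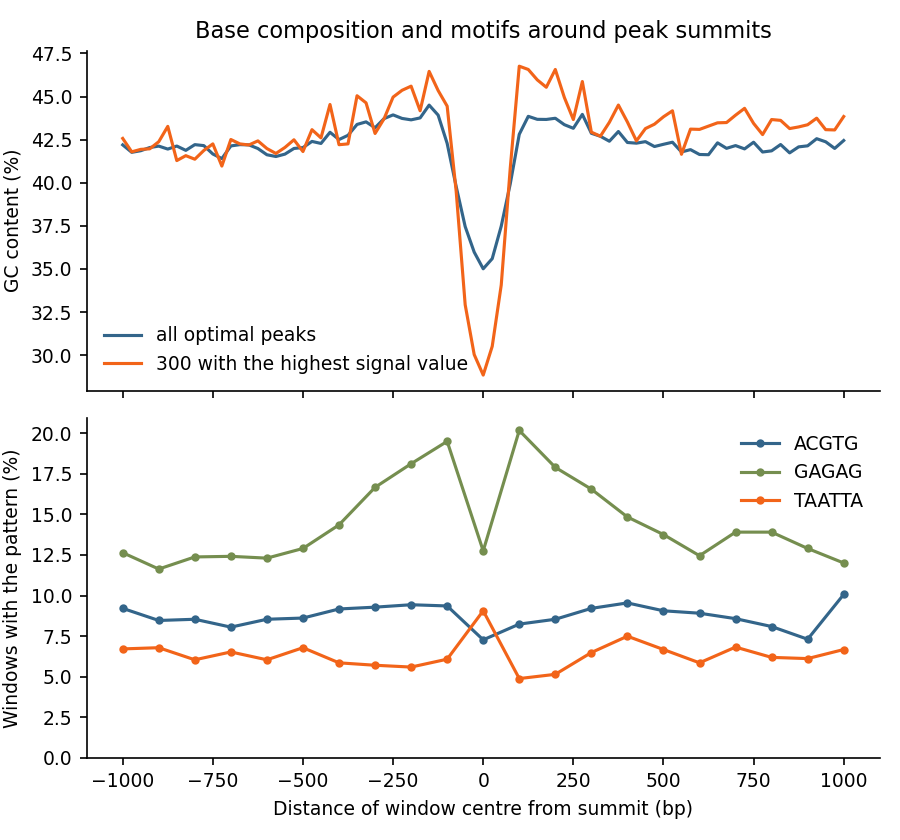
Upper panel, mean GC content (%) of windows at distances up to 1000 bp from the summits of all optimal peaks and of the 300 with the highest signal value. Lower panel, share of windows (%) of 101 bp that hold ACGTG, GAGAG or TAATTA, centred at each distance (bp); at the summit the shares are 7.27%, 12.8% and 9.06%.

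Midline genes were examined because Sim directs their expression. Of the 14 listed, 8 carried an optimal peak. The strongest was at aos, an EGFR antagonist gene, in an intron (3L, 16480470 to 16480640, signal value 302), followed by S, which encodes the chaperone Star, also in an intron (2L, 1072349 to 1072436, 219) and sim itself (212). Further peaks lay in an intron of sli, the midline repellent Slit (112), and between genes near oc (84.7), glec (76.2), wrapper (72.2) and D (71.7). The best peaks of aos, S, sim and glec were overlapped in both replicate lists, those of sli and D only in replicate 2, that of oc only in replicate 1, and that of wrapper in neither. Tl, rho, btl, vvl, en and mfas carried no peak. The best peaks of sim and D held ACGTG within 50 bp of the summit. The count of 8 compared with a mean of 5.53 (SD 1.80) in random lists of like gene length and did not pass the threshold (permutation adjusted p = 0.513). The list passed when each peak was given to the gene with the nearest TSS (8 genes, random mean 3.20, permutation adjusted p = 0.0347). These need not be the same 8 genes, because the only peak within 5 kb of wrapper had its nearest TSS at CG13506.

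Ribosomal protein genes carried peaks more often than genes of like length, with 11 of 14 against a random mean of 3.75 (permutation adjusted p = 0.00340). Among the best peaks in that list were those near RpL3 (282), RpL32 (125) and RpL13 (113), of which that near RpL3 had its nearest TSS at CG17726. In replicate 1 alone 6 of the 14 carried a peak against a random mean of 1.90, and the permutation adjusted p was 0.0839. Among the 1341 strongest peaks 7 did against 2.31 (0.0663), and with genes extended by 10 kb 11 did against 5.80 (0.167). Glial genes carried peaks in 8 of 9 cases against 3.31 (permutation adjusted p = 0.0215), with the strongest near moody (223), pnt (135), Gs2 (128) and nrv2 (97.2). The glial call ended in replicate 1 alone (4 genes, permutation adjusted p = 0.483), among the 1341 strongest peaks (4, 0.422) and in the conservative list (7, 0.0901). It also ended with genes extended by 1 kb (6, 0.0782) or 10 kb (8, 0.203) and with the nearest TSS (5, 0.103). Notch pathway genes did so in 11 of 15 cases against 5.10 (permutation adjusted p = 0.0215), with the strongest near E(spl)m7-HLH and E(spl)m8-HLH, which share a peak of 218 in an intron near a TSS of gro, and near numb (159) and E(spl)mdelta-HLH (141). Neighbouring genes of the E(spl) complex share peaks. When genes with overlapping windows were counted once, 6 of 10 carried a peak against a random mean of 4.02 and the permutation adjusted p was 0.686. The Notch call also ended with genes extended by 1 kb (7 against 3.39, permutation adjusted p = 0.127) or 10 kb (11 against 6.63, 0.203). With the nearest TSS it ended too (6 against 2.88, 0.167).

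The other lists did not pass the threshold with genes extended by 5 kb, but some did under alternatives. EGFR pathway genes carried peaks in 10 of 13 cases (permutation adjusted p = 0.0874), and beyond aos and S the strongest were at edl (204) and aop (199). The EGFR list passed with the conservative list (11 genes, permutation adjusted p = 0.0181), with 1 kb either side (10, 0.0204), with the nearest TSS (10, 0.00510) and when matched on the number of TSS (10, 0.0408). Axon guidance genes did so in 11 of 14 (permutation adjusted p = 0.0874), led by NetA (162), NetB (141), Sema1a (138) and fra (130), and heat shock genes in 6 of 9 (adjusted p = 0.0874), led by Hsp23 and Hsp27, which share a peak of 280, Hsp83 (190) and Hsp22 (77.8). Heat shock genes passed with 1 kb either side (5, permutation adjusted p = 0.0465) and with the nearest TSS (5, 0.0170) but not when genes with overlapping windows were counted once (3 of 6 against 1.85, 0.748), and axon guidance and germline genes when matched on the number of TSS (0.0408 for each). Germline genes did so in 6 of 7 (permutation adjusted p = 0.0578), with the strongest near bam (158), aub (98.8), piwi (90.6) and nanos (76.8). The best peaks near bam and aub had their nearest TSS at RpS27 and RpL9, and no germline gene had a TSS nearest to a summit. Counts were 8 of 12 for bHLH-PAS genes (permutation adjusted p = 0.383; sim 212, gce 141, sima 105, trh 90.8), 4 of 10 for trachea (adjusted p = 1; rib 134, trh 90.8, bnl 55.2, dysf 50.8) and 6 of 13 for dorsoventral patterning (adjusted p = 0.971; ths 120, dpp 114, Dr 108, brk 69.2).

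Among markers of other cell types, neurons had 4 of 12 genes with a peak (permutation adjusted p = 0.767), near elav (215), Gad1 (105), ChAT (96.5) and Syx1A (78.4). Muscle had 7 of 14 (permutation adjusted p = 0.852), with best peaks near Mef2 (265), tin (183), Tm1 (172) and how (120). Epidermis had 4 of 8 (permutation adjusted p = 0.971), near grh (185), shg (79.5), ovo (75.8) and ple (64.7), and gut endoderm had 3 of 6 (adjusted p = 0.971), near fkh (140), cad (121) and GATAe (68.5). Hemocytes and fat body had 2 of 10 (permutation adjusted p = 0.589), near Lsp2 (165) and Hml (118). Segmentation and Hox genes had 7 of 18 (permutation adjusted p = 1), with the strongest at Antp (130), slp1 (100.2), lab (69.5) and Ubx (65.4). With the nearest TSS 10 of the 18 had a peak against a random mean of 4.23 and passed (permutation adjusted p = 0.0212). Several best peaks lay outside the listed gene and had their nearest TSS at another. These were Mef2 (Pal1), Tm1 (CG4338), Gad1 (wit), nrv2 (nrv1), Hml (CG8745), Lsp2 (yps), ple (CG8519), cad (Pomp), nanos (Nsun5), piwi (CG12253), Hsp22 (Hsp26), Hsp23 (Hsp27), E(spl)mdelta-HLH (CG43116), wrapper (CG13506) and glec (Gr93d). Those of NetA (sbm), NetB (hog), fra (CG33752) and ChAT (CG34283) lay within the listed gene but nearest to another TSS. Of all protein-coding genes 30% carried a peak.

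**Figure D3:**
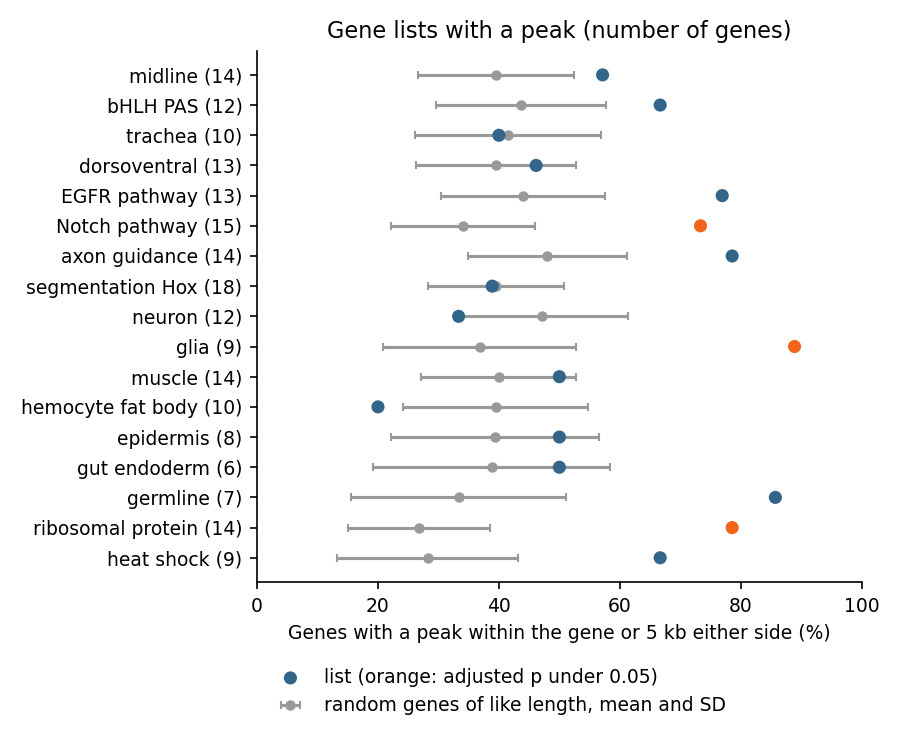
Share of genes in each of the 17 lists (y axis, number of genes in parentheses) with an optimal peak within the gene or 5 kb either side (x axis, %), in colour, and the mean and SD of random lists of like gene length in grey. The lists for the Notch pathway, glia and ribosomal proteins, in orange, have an adjusted p under 0.05.

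The locus of sim was examined because the tagged gene is itself known to be regulated by Sim and because the transgene adds DNA from this region. The gene spans 13057755 to 13078124 on the plus strand of 3R. Within 50 kb of it lay 10 optimal peaks, against 2.41 expected from the length of the gene with 50 kb either side, and 7 lay within 20 kb. The replicate lists held fewer, 2 in replicate 1 and 5 in replicate 2 within 50 kb. The strongest, from 13068093 to 13068396 in an intron, had a signal value of 212 and ranked 161 of 2682 in the optimal list. It ranked 87 of 1071 in replicate 1 (118) and 275 of 1676 in replicate 2 (95.4). Further peaks of the optimal list lay in introns of sim (66.9 and 55.9) and 435 bp from its TSS (84.4). Outside the gene, peaks were nearest to CtBP (63.2), ry (68.7 and 63.9), snk (46.8 and 18.1, which overlap each other) and CG7966 (65.0). The number of peaks at this locus was not tested.

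**Figure D4:**
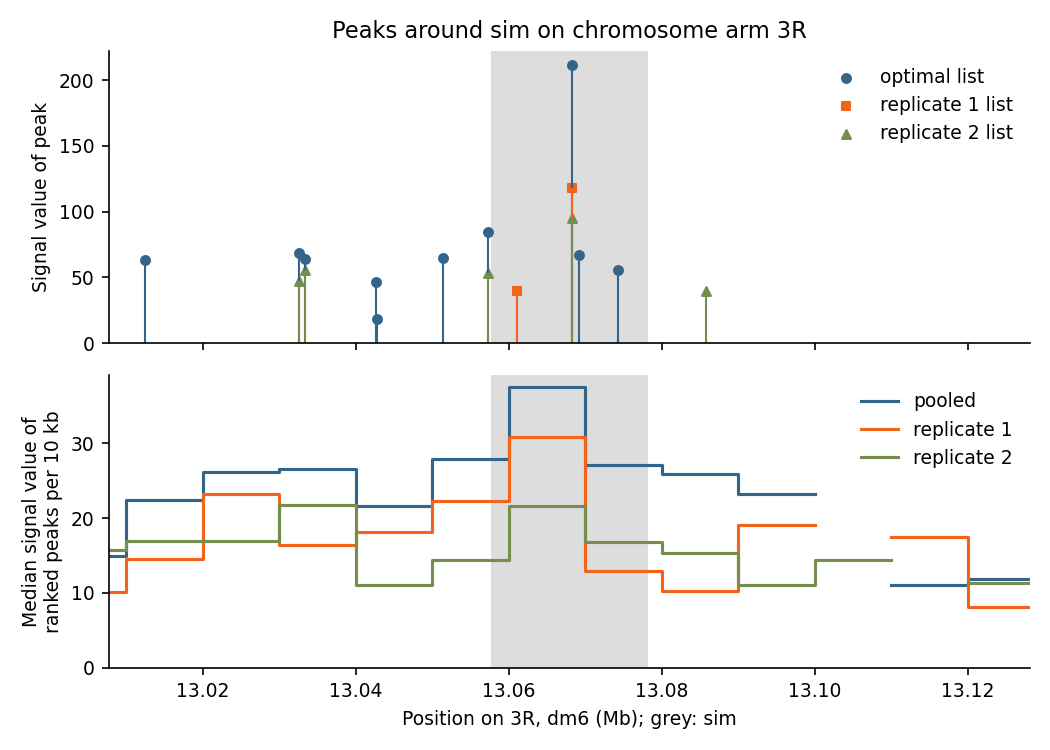
Upper panel, signal values of peaks within 50 kb of sim (grey) by summit position on 3R in the optimal list and each replicate list. Lower panel, median signal value of ranked peaks per 10 kb, pooled and per replicate; the strongest peak, of signal value 212, lies within sim.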

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

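The window around sim and all tests on it were chosen only after the raised signal was seen, and the need for both replicates to exclude a domain rich in called peaks was added after the pooled result.

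Ranked peaks outside the optimal list, which served above only as a background for TSS proximity, stood high around sim. In the window of 80370 bp from 13027755 to 13108124 on 3R, which holds sim and 30 kb either side, 78 such peaks had a median signal value of 26.8, against a median of 17.0 over 1482 other windows of that length, none of which reached it. The window stood at the 99.9th percentile in replicate 1 and the 98.5th in replicate 2, but the replicates make up the pool in which the raised signal was seen, so these values do not decide whether extra copies of the locus carried by the transgene are its source. Among 19 windows with at least as many optimal peaks it was highest in the pooled list and in replicate 1 but at the 68.4th percentile in replicate 2, so a domain rich in called peaks stays open as well because the replicates differ. Binding of the fusion at its own locus stays open, and no biological explanation was tested. The control experiment, which would show extra copies, was not analysed here.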

How the results depend on the processing

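Alternatives chosen after seeing the data were merged peaks, windows of equal GC content, ranked peaks as background, genes counted once, 10 kb either side of genes for lists other than the midline, matching on the number of TSS, and the midline list without sim. Of the principal values recomputed under alternatives, 51 stayed within the bounds set, 11 moved beyond them, 2 became weaker, 1 stronger and 1 reversed. Of peak counts at named genes 273 stayed and 101 moved. The count of peaks was 1341 in the stronger part of the optimal list, and 1071 to 1676 in the single replicate lists, which follows from shorter lists. Spearman's correlation of signal values between replicates was 0.551 with the ranked lists. The CME core difference was -2.31 percentage points (exact adjusted p = 0.0786) in the stronger part and ranged from -4.71 to -1.77 in the single replicate lists, and it turned to 0.508 against windows of equal GC content. There the number of 6-mers more frequent at summits was 103. Of the 16 lists other than the midline, 3 passed the threshold, against 1 in the stronger part, 1 to 3 in the single replicate lists, 0 with 10 kb either side and 6 when genes were matched on the number of TSS. With the nearest TSS 4 passed, of which only the ribosomal protein list was among those 3. Midline genes numbered 8, not necessarily the same ones, and passed the threshold (permutation adjusted p = 0.0347) when peaks went to the gene with the nearest TSS. Over the other alternatives the adjusted p ranged from 0.221 to 1. Their count was 5 in the replicate 1 list (random mean 2.91) and 6 in the replicate 2 list (4.13). The X share was 17.9% to 18.5% in the single replicate lists. Except where stated, the cause was not tested. TSS proximity and replicate overlap passed under every alternative run. Depth is unknown and its effect was not tested. No paired analysis was possible because the series holds 1 group.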

Other observations

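The gene families, both tests of genes away from the strongest peaks, the heptamer with its base composition test, and the tests against GC content were chosen only after the data were seen. The tests of masked repeats, of promoters and of the CME core at midline genes were written before their results.

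Families defined by gene symbol extended the ribosomal protein result. Of 92 cytoplasmic ribosomal protein genes 61 carried a peak, against a mean of 22.7 in random lists of like gene length (permutation adjusted p over 13 sets = 8.67e-04), with peaks near RpL3 (282), RpL27 (229) and RpL35 (195). All 7 bHLH repressor genes of the E(spl) complex carried a peak against 1.49 (permutation adjusted p = 8.67e-04), but with overlapping windows counted once they were 2 of 2 (0.145). These 7 genes are all members of the Notch pathway list, and their peaks had been seen there before the family was formed. Their count thus repeats part of the Notch result and adds no support to it. Fewer peaks than in random lists were found at cytochrome P450 genes (9 of 85 against 25.4, permutation adjusted p = 8.67e-04) and odorant receptor genes (5 of 59 against 15.5, 0.00416). Within 1 kb of the gene neither passed, although both counts stayed below the random mean (6 against 12.1, 0.141, and 2 against 7.02, 0.124). Gustatory receptor genes (8 of 60 against 16.3, permutation adjusted p = 0.0260) and cuticle protein genes (9 of 70 against 17.2, 0.0306) also had fewer. Neither passed when genes with overlapping windows were counted once (5 of 37 against 10.1, 0.127, and 4 of 34 against 9.38, 0.0906). Proteasome genes (10 of 48 against 12.1, permutation adjusted p = 0.721), complex I genes (11 of 40 against 9.91, 0.884) and robo receptor genes (2 of 3 against 1.38, 0.888) did not pass the threshold.

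The hypothesis that mitochondrial ribosomal protein genes carry peaks more often than genes of like length arose from mRpS10 and mRpL41, which with mRpS23 lie within 5 kb of the 30 strongest peaks. Of all 73 such genes 29 carried a peak against a random mean of 16.1, and without those 3 the count was 26 of 70 against 15.5 (permutation adjusted p = 0.0104). Within 1 kb of the gene 7 of the 70 did, against 5.74 (permutation adjusted p = 0.764). Some best peaks had the same signal value as those of cytoplasmic ribosomal protein genes. These were mRpS22 and RpL4 (96.4), mRpL27 and RpL27A (80.9), mRpL50 and RpL18 (73.2), and mRpL44 and RpL35A (62.6). The counts of both families are therefore not independent. The hypothesis that Polycomb and trithorax group genes carry peaks more often arose from peaks noticed at ph-p, Psc, RYBP, osa, tara and Chro. Of all 28 listed, 19 carried a peak against 10.9 (permutation adjusted p = 0.00693), a count that includes those genes, and within 1 kb 14 did against 7.56, which did not pass (0.0702). Among the 21 left without them and without ash1, which lies within 5 kb of the strongest peak but 1, 12 did against 7.88, which did not pass (permutation p = 0.0990). These included phol (366), Pc (345) and Trl (327).

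Whether peaks at midline genes hold the CME core more often than other peaks was also tested. Of 20 such peaks 3 held ACGTG within 50 bp of the summit (15%), against 7.21% of 2662 others. The odds ratio was 2.27 (95% interval 0.422 to 7.95, two-sided Fisher's exact p = 0.174), which leaves the question open.

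The lower frequency of the CME core at summits than in flanks was weighed against base composition. Against genomic windows of equal GC content the ratio of summit windows with ACGTG was 1.08 (permutation p = 0.310), so the AT-rich bases of summits may account for the lower frequency. Windows centred 100 bp either side of the summit gave a ratio of 1.06 (permutation p = 0.201), which does not decide whether summits were called beside sites of the core. No biological explanation was tested.

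Sites of a 7-base word beside summits had a fixed orientation, a pattern seen on all arms before the test, so that the arms are not independent of each other. Among 11380 words tested between 40 and 120 bp from summits on 2L and 2R, with overlapping peaks merged, TACACTG had the smallest p, with 85 sites read toward the summit and 3 away. On the other arms 133 of 143 sites (93.0%, exact 95% interval 87.5% to 96.6%) read toward it, compared with 12 of 21 at 400 to 480 bp. A-rich words were oriented too, such as AAAAAAA (606 toward and 256 away). So were words that hold CACTG, as TACACTG does, or its reverse complement CAGTG. On the other arms ACAGTGG had 162 sites toward and 15 away, CACTGAG 94 and 10, and TGCACTG 123 and 33. Where ACAGTGG reads toward the summit, the bases CACTG on its other strand read away from it. The shared bases thus did not have the same orientation in all these words. The orientation was therefore not particular to TACACTG. As a set, 629 other words of the bases of TACACTG read toward the summit at 49.8% of 12803 sites, which argues against base composition for TACACTG. These words hold A and T equally often, so they cannot speak to base composition for the A-rich words. More than 500 bp from a TSS the share for TACACTG was 92.0%, which argues against promoter architecture. Among peaks with no masked base it was 88.9% of 9 sites, too few to exclude repeats masked in the assembly. No biological explanation was tested.

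Of 87 optimal peaks with a signal value under 20, 86 overlapped a stronger listed peak.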
